A study of Mus musculus with 1187 samples.

How the data were processed

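Brain endothelial cells of adult C57BL/6 mice were sorted singly into 384-well plates on a green reporter driven by Cldn5, a gene of the endothelial tight junction, and on absence of a red reporter driven by Cspg4, a gene of pericytes and oligodendrocyte precursors. Full-length cDNA was made by the Smart-seq2 method, in which each well is a separate library without molecular identifiers. The labels name 590 cells from heterozygous Pdgfb ret/+ mice and 597 cells from Pdgfb ret/ret mice, in which loss of the retention motif of PDGF-B leaves the brain short of pericytes. No label names an animal.

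The deposited table held whole-number counts of reads per gene for 46517 genes and 1187 cells. Per the submitters' processing notes, TopHat2 2.1.1, SAMtools 0.1.18, featureCounts and Subread 1.4.6-p5 were used with the GRCm38 and mm10 builds; strand handling is not given in the sources used here, so reads of overlapping antisense genes could not be told apart. The table held no spike-in rows and no row of a reporter gene. Coordinates given in the text are from GENCODE M21, which is on GRCm38.

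The columns of the table are named by plate and well, and the labels number the cells without a plate or well. No column could therefore be given a genotype, and none was guessed from order, number or values. Plates 521 and 522 together hold 590 columns and plates 523 and 524 hold 597, the numbers of ret/+ and ret/ret labels, but equal numbers do not show which cells are on a plate. The comparisons of ret/ret with ret/+ cells that had been planned before the data were examined could not be made and no value for them is given. The 1187 cells were treated as 1 pooled sample with plate (521, 522, 523 and 524) as batch. Plate may coincide with genotype or animal, so values are given plate by plate and no groups of plates were formed. With 1 sample there was no test and no p-value, and cells were not used as replicates.

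The planned filter on cells, at least 50000 reads and 1000 genes with a read, removed none. No doublet caller was run. Counts were scaled to the total of the cell or sum (CPM). Cells were clustered with scanpy 1.11.5 (Leiden, python-igraph 0.11.9, resolution 1, 15 neighbours, 30 principal components, 2000 variable genes). Variable genes came from 4854 candidates: a seeded random subset of the genes, read in at least 10% of cells, without the fixed pathway lists, sex-linked and mitochondrial genes, and without genes over 2-fold apart between any 2 plates. Genes that were not used for clustering were held out, and only these were ranked between clusters. The subset, the detection filter, the plate filter and the naming rule were settled after clusters had been looked at, by clarity of markers: 11 settings of the variable genes and 3 naming rules were viewed, each rule under several clustering settings. The list of these was written afterwards from the commands that had been run. A cluster was named from markers fixed before the data were examined. At least 3 markers, and at least the share 0.5 of those detected, had to be 1.5-fold higher than in all other cells. A marker of its own had to be among its 10 leading genes. For the name of another cell type, 3 of that type's markers had to be among them. A cluster led by more markers of another class than of its own stayed unnamed. Some clusters had no name by these rules. Those of them in which at least the share 0.7 of capillary markers was higher, by any amount, are called capillary-marker clusters. They are kept by number, because none of the capillary markers was among their leading genes.

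Values for a class are CPM of counts summed over its cells, with exact Poisson intervals. Log2 ratios use a prior of 1 CPM on both sides. Shares carry exact Clopper-Pearson intervals at 95%, except that the limit beside a count of 0 cells is 3 counts of the total. Reads of a Smart-seq2 library are not independent molecules and cells vary in bursts, so all such intervals cover counting error only; the range over plates is the wider guide. Where a side had 0 reads, the log2 ratio rests on this prior. Members of the fixed pathway lists counted as measured at 5 CPM or more on either side; members that are also class markers were left out of list medians because they had named the classes, a choice that was not in the plan and was made before list medians were computed. Each median was set among 10000 random lists of the same size matched on mean expression and drawn from held-out genes; this percentile describes these cells and is not a test. Within-plate ratios were given where both classes had at least 10 cells on the plate. For shares of cells with a read, each cell was thinned to 100000 reads, which lost no cell.

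The planned rule for named genes was applied between classes: at least 20 CPM on either side, a read at fixed depth in at least 10% of the cells of the higher class, and the same direction in the mean of each cell's own CPM and in the share of cells at fixed depth. The 12 highest and 12 lowest log2 ratios were named between arterial-like and venous-like cells and 6 each way in other comparisons. Sex-linked and mitochondrial genes, unnamed models and class markers were left out. Cavin1, Cavin2 and Cavin3 stand in the table as Ptrf, Sdpr and Prkcdbp; all 273 list genes were present.

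The ratio step was tested on simulated cells with the numbers and depths of the arterial-like and venous-like cells. Each gene's mean and variability came from both classes pooled. Genes were drawn independently, without plate differences, and the classes were given, so the simulation does not test the clustering. Of 50 genes made 4-fold different among the 8299 genes in the step, 100% had the right direction, as had 96% of 50 genes made 1.5-fold different; unchanged genes had an SD of 0.39 on the log2 scale. Alternatives were the mean of each cell's own CPM, TMM factors (edgeR 4.0.16, R 4.3.3), other cell filters, thinning, a prior of 5 CPM, no filter on low values, other resolutions and variable genes, and each plate left out in turn. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19 and matplotlib 3.10.9.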

Results

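The table held 418924921 gene-assigned reads from 1187 sorted brain endothelial cells. Cells had between 100779 and 584112 reads (median 360947) and between 1402 and 11043 genes with a read (median 4462). Plates 521, 522, 523 and 524 held 300, 290, 285 and 312 cells with median depths of 373444, 349607, 364499 and 355056 reads. Mitochondrial transcripts took between 1.31% and 1.47% of the reads of a plate. The study set brains with normal pericyte cover against brains short of pericytes; because no cell could be assigned a genotype, the values below describe the cells of both genotypes together, and comparisons are between kinds of endothelial cell.

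Pdgfb, the gene altered in these mice, encodes the growth factor by which endothelium recruits pericytes (chromosome 15, 79995874 to 80014977, minus strand). It stood at 188.7 CPM over all cells (95% counting interval 187.4 to 190.0), with 214.8, 165.2, 205.9 and 167.7 CPM on plates 521 to 524. At 100000 reads per cell, 60.5% of cells had a Pdgfb read (57.6% to 63.3%); without thinning it was 65.5%. The retention motif is a small part of the gene, so a gene count does not show the genotype.

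The sorted cells carried the transcripts of brain endothelium at high level. Cldn5, the main claudin of the blood-brain barrier (chromosome 16, 18776847 to 18778262), reached 4038 CPM and had a read in 100% of cells at fixed depth (99.7% to 100%). The organic anion transporter Slco1a4 reached 3608 CPM, the VEGF receptor Flt1 3455 CPM and the glucose transporter Slc2a1 3432 CPM. All 20 barrier transporters were at 20 CPM or more, with a median of 939.7 CPM, as were 13 of the 14 junction genes, with a median of 585.2 CPM. Transcripts of other cell types were mostly low. The most abundant marker was Rgs5 for pericytes (32.4 CPM), Myl9 for smooth muscle (7.85), Dcn for fibroblasts (6.80), Nrgn for neurons (6.89), Ptprc for other leukocytes (1.69), Alas2 for erythroid cells (6.70), Ttr for choroid plexus (17.7) and Prox1 for lymphatic endothelium (1.57). Gja1 of the astrocyte list stood at 185.3 CPM, but the median of that list was 12.9 CPM, and that of the microglia list was 2.97 CPM. Cells with at least 3 markers of another type at 100 CPM or more numbered 8 for microglia, 7 for pericytes, 7 for astrocytes, 6 for erythroid cells and 2 for fibroblasts. For smooth muscle, oligodendrocytes, neurons, other leukocytes, choroid plexus and lymphatic endothelium it was 0 of 1187 cells, which allows a share of up to 0.253% by the floor of 3 counts. No cluster had 3 markers of another cell type among its 10 leading genes. The interferon response list had a median of 136.4 CPM and the cycling list of 3.37 CPM, and no cluster took either name, although the arterial-like cluster had 6 of 12 interferon response markers at least 1.5-fold higher than other cells (median log2 ratio 0.60).

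Clustering gave 9 groups of cells. Cluster 8, the arterial-like cells, had all 15 detected arterial markers at least 1.5-fold higher than other cells, with Fbln5, Mgp and Eln among its leading genes. Cluster 0, the venous-like cells, had 10 of 11 venous markers higher, including the venous transcription factor Nr2f2. Cluster 5, called angiogenic-like, had 8 of 9 markers of sprouting endothelium higher. Of its 105 cells, 38 and 50 lay on plates 521 and 522. Over all cells, the 13 listed markers of this kind summed to 2539, 2235, 1662 and 1740 CPM on plates 521 to 524. Capillary markers were higher by any amount in clusters 1 (10 of 10 markers, 5 of them at least 1.5-fold) and 2 (9 of 10, with 4 at least 1.5-fold). Cluster 5 also had 7 of 10 higher, with 3 at least 1.5-fold, but already had its name. Over all cells, the 10 capillary markers summed to 7231, 8581, 11220 and 10840 CPM on plates 521 to 524. Of the 139 cells of cluster 2, 33, 13, 42 and 51 lay on these plates. The marker counts behind all cluster names were taken over plates pooled and not within plates, so plate differences may enter them. Pericyte transcripts were also higher in clusters 1 and 2, which serve as the reference below, than in all other cells pooled over plates. Cluster 1 had its 1 detected pericyte marker, Rgs5, at least 1.5-fold higher (log2 ratio 1.59) and among its leading genes. Cluster 2 had 2 of 2 higher (median 0.94). Of the 219 cells of cluster 1, 81 and 110 lay on plates 523 and 524, where Rgs5 was highest. Within these plates, 30.9% and 38.2% of its cells had a read of any pericyte marker at fixed depth. Other clusters with at least 10 cells there had 26.7% to 50.0% and 30.0% to 39.2%. Clusters 3, 4, 6 and 7 stayed unnamed. Cluster 3 (97 cells) had the microglial gene Cx3cr1 and the choroid plexus gene Ttr among its leading genes. It had 3 of 3 detected microglial markers at least 1.5-fold higher than all other cells (median log2 ratio 1.96). The same held for 3 of 3 detected pericyte markers (median 1.21). It missed the microglial name because only Cx3cr1 of that list was among its leading genes. Cluster 4 (38 cells) had 5 of 5 detected fibroblast markers higher, with a median log2 ratio of 3.63 to all other cells. Arterial-like cells were 14.4% of all cells (171 of 1187, 12.5% to 16.5%), venous-like cells 14.2% (169 cells, 12.3% to 16.4%), angiogenic-like cells 8.85% (105 cells, 7.29% to 10.6% by counting error alone) and the capillary-marker clusters together 30.2% (358 cells, 27.6% to 32.9%). These shares depended on the clustering, far beyond these intervals. The angiogenic-like share was 19.6% with 4000 variable genes, 3.71% with variable genes from all genes, 19.6% without plate 522 and 15.0% without plate 523. At resolution 0.5 the capillary-marker share was 62.3% and no cluster was venous-like or angiogenic-like, and no cluster was venous-like with 4000 variable genes or when plate 523 or 524 was left out. They also differed by plate. The angiogenic-like share was 12.7%, 17.2%, 4.21% and 1.60% on plates 521 to 524, and the capillary-marker share 13.0%, 12.1%, 43.2% and 51.6%. Arterial-like cells ranged from 10.0% to 17.0% and venous-like cells from 9.00% to 19.3% over plates. Sorting on Cldn5 and onto plates can itself set such shares, as can naming clusters by markers that differ between plates.

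**Figure D1:**
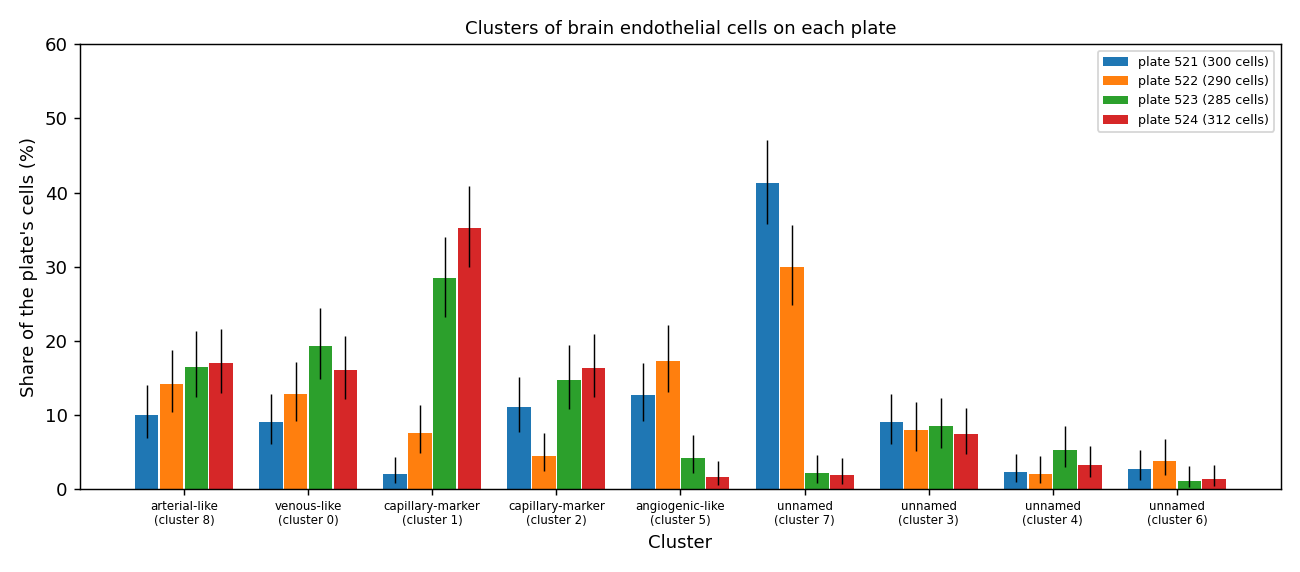
Share of each plate's cells (y axis, percent) in each of the 9 clusters (x axis), with 1 bar per plate; error bars are exact 95% binomial intervals, which cover counting error only. Cluster 7 holds 41.3% and 30.0% of cells on plates 521 and 522 and about 2% on plates 523 and 524.

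Arterial-like and venous-like cells were compared over genes that had not formed the clusters. The highest in arterial-like cells were the calcium pump Atp2a3 (161.5 CPM against 1 read in all venous-like cells), the estrogen-binding receptor Gper1 (150.3 CPM against 1 read), the collagens Col18a1 (199.1 against 0.463 CPM, log2 ratio 7.10) and Col14a1 (155.7 against 0.182 CPM, 7.05) and the cadherin Cdh13 (6.11). They were followed by the anion transporter family member Slc26a10 (5.99), the long noncoding RNA Mannr (60.2 CPM against 1 read), the alkaline phosphatase Alpl (851.9 against 13.4 CPM, 5.89), the fibrillin Fbn1 (51.8 CPM against 1 read), Syt15 (5.63), Laptm5 (5.57) and the nucleotide receptor P2ry2 (44.7 CPM against 0 reads, 5.52). The log2 ratio of P2ry2 was 1.34 with variable genes from outside the subset. Several of these transcripts were read in a minority of arterial-like cells at fixed depth: P2ry2 in 12.3%, Mannr and Fbn1 each in 23.4% and Gper1 in 29.8%. Alpl had a read at fixed depth in 77.8% of arterial-like and 4.73% of venous-like cells. It lies on chromosome 4 from 137741733 to 137796384 on GRCm38, and Atp2a3 on chromosome 11 from 72961169 to 72993044.

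Higher in venous-like cells were the apelin receptor Aplnr (101.5 CPM against 2 reads in all arterial-like cells), the retinaldehyde dehydrogenase Aldh1a1 (100.3 against 0.064 CPM, log2 ratio -6.57), coagulation factor F5 (67.9 CPM against 2 reads), Gpr182 (-4.80), Ddit4l (-4.55), Bst1 (-4.31), the class II chaperone Cd74 (-4.10, but 0.26 with variable genes from outside the subset), the laminin Lama1 (-4.04), Flrt2 (282.6 against 17.2 CPM, -3.96), the amino acid transporter Slc7a3 (-3.96), the transcription factor Sox9 (-3.82) and the alcohol dehydrogenase Adh1 (329.2 against 23.6 CPM, -3.75). Flrt2 had a read in 53.8% of venous-like and 8.77% of arterial-like cells, and Adh1 in 54.4% and 9.94%. Others were read in few venous-like cells: Aplnr in 20.1%, F5 in 19.5% and Gpr182 in 12.4%. Aldh1a1, Ddit4l and Slc7a3 were each read in 11.2% and Cd74 in 10.1%, close to the 10% required. Aplnr lies on chromosome 2 from 85136225 to 85139923 and Adh1 on chromosome 3 from 138260991 to 138290698. All 24 genes had the same direction within each of the 4 plates except Cd74, with 3 of 4. Genes in this and the later comparisons were picked by ratios pooled over these same plates, so such agreement is not independent evidence. Over plates, P2ry2 ranged from 0.24 to 6.62 and Ddit4l from -5.93 to -0.12. Under the other settings that gave a value, all but Cd74 kept their direction, but many ratios weakened. The weakest were, for example, 4.26 for Atp2a3, 2.88 for Slc26a10, 1.89 for Mannr, 1.59 for Syt15, -1.30 for Ddit4l and -1.01 for Slc7a3.

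For each list median, the range after the word alternatives holds its lowest and highest value under the other settings tried. Of the fixed gene lists, Notch signalling stood highest in arterial-like relative to venous-like cells. Its 6 members outside the class markers had a median log2 ratio of 1.01 (percentile 100.0 among matched random lists; 1.09 to 1.63 within plates, alternatives 0.91 to 1.72), with the ligands Jag2 at 2.30 and Jag1 at 1.76 and the receptor Notch4 at 1.53. Of these members, 3 were at least 1.5-fold higher and 0 lower. The TGF-beta/BMP list had a median of 0.44 (percentile 99.6; 0.23 to 0.97 within plates, alternatives 0.27 to 0.695), with 3 of 9 members at least 1.5-fold higher and 0 lower. Smad6, an inhibitor of BMP signalling, was at 2.80, the ligand Bmp6 at 1.18 and the pseudoreceptor Bambi at -0.58. The basement membrane list had a median of 0.29 (percentile 98.2, alternatives 0.083 to 0.38) with 4 of 12 members higher and 3 lower; its plate medians ran from -0.12 to 0.33.

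In the list median, barrier transporters were lower in arterial-like than in venous-like cells. Their median was -0.51 (percentile 0.0; -0.89 to -0.33 within plates, alternatives -0.64 to -0.23), with 6 of 15 members at least 1.5-fold lower and 1 higher. The organic anion transporter Slc22a8 was at -1.77 and the amino acid transporters Slc38a3 and Slc7a1 at -1.71 and -1.23, while the taurine transporter Slc6a6 was at 0.85 and Slc2a1 at -0.09. The leukocyte adhesion and inflammation list had a median of -0.84 (percentile 0.1) with 6 of 10 members lower and 0 higher. It was -1.61 at resolution 2.0 and -0.079 with variable genes from outside the subset, and had plate medians of -0.94, -1.01, -0.23 and 0.00. Its immunoglobulin-family member Icam2 was at 0.34. The immediate early and dissociation stress list had a median of -0.26 (percentile 1.3, alternatives -0.49 to -0.047) and changed direction by plate, with 0.67, 0.47, -0.58 and -0.88 on plates 521 to 524. Medians of the remaining lists were -0.05 for junctions (percentile 41.0, 0 members higher and 2 lower of 13, alternatives -0.14 to -0.003), -0.13 for Wnt/beta-catenin (14.7, 1 and 2 of 14, alternatives -0.31 to -0.016) and 0.24 for caveola and vesicle genes (92.7, 2 and 0 of 7, alternatives 0.064 to 0.40). They were 0.03 for VEGF and TIE receptor signalling (64.0, 1 and 1 of 8, alternatives -0.14 to 0.215), -0.02 for shear response (49.8, 0 and 0 of 4; 0.79, 0.32, -0.25 and -0.32 on plates 521 to 524, alternatives -0.10 to 0.21) and -0.09 for hypoxia and glycolysis (35.0, 2 and 2 of 9, alternatives -0.23 to 0.089). Within these, Sox17, an arterial transcription factor, was at 1.14 and the Wnt antagonists Apcdd1 and Nkd1 were at -1.58 and -1.70.

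**Figure D2:**
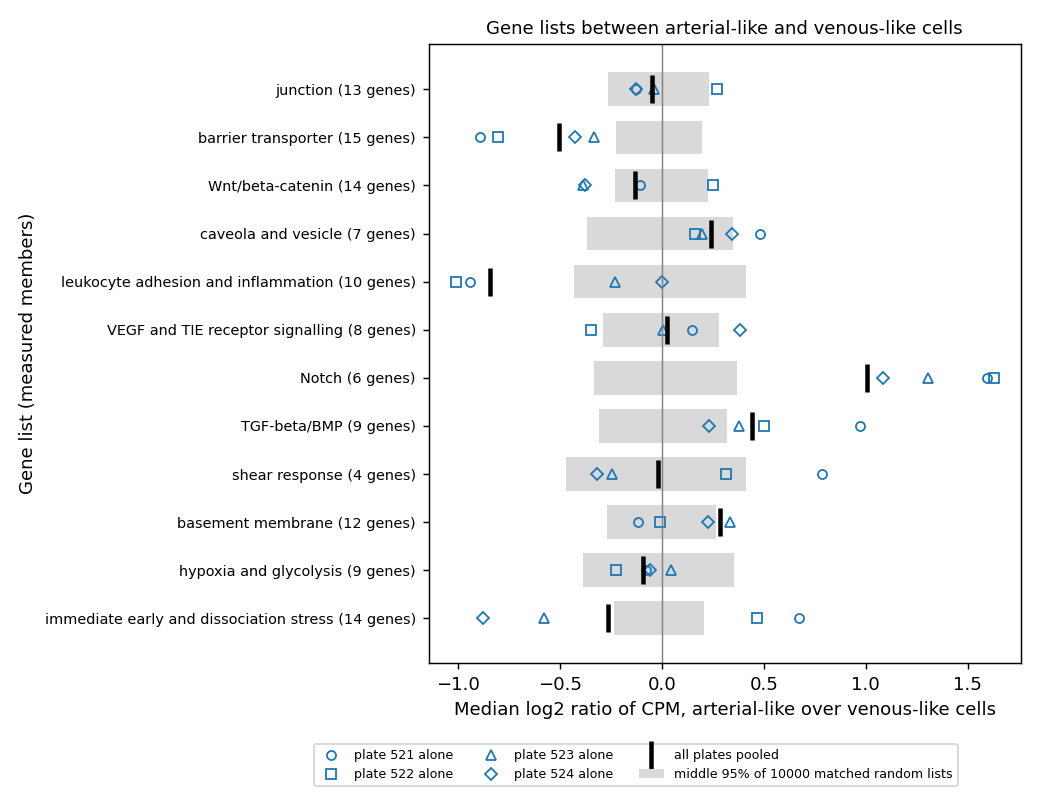
Median log2 ratio of CPM, arterial-like over venous-like cells (x axis), for each fixed gene list (y axis, measured members in parentheses). The black mark pools all plates, open symbols are single plates, and the grey bar holds the middle 95% of matched random lists. The bar comes from ratios pooled over plates, so it gives no standing for a single plate. Notch lies right of 0 and barrier transporters left of 0 in every plate. The immediate early list lies on opposite sides of 0 by plate.

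Arterial-like cells set against the capillary-marker clusters had fewer transcripts of most listed barrier transporters and more of caveola and Notch genes in the list medians. Nos1, the neuronal nitric oxide synthase, was at 159.4 against 0.26 CPM (log2 ratio 6.99), and Nipal2 (5.53), the desmosome protein Dsp (5.38), Fbn1 (5.35), Laptm5 (5.30) and the transcription factor Plagl1 (5.26) followed. At fixed depth, Nos1 had a read in 31.6% of arterial-like cells and Plagl1 in 10.5%. Ddit4l (-4.82), the sulfotransferase Chst2 (-3.38), Angel1 (-3.31), the sterol exporter Abcg1 (-3.20), the repressor Prdm1 (-2.97) and Ankrd37 (-2.96) were lower; Plagl1 and Ddit4l had their direction in 3 of 4 plates and the others in 4 of 4. The barrier transporter median was -0.69 (percentile 0.0; -1.48 to -0.55 within plates, alternatives -1.08 to -0.55), with 10 of 15 members lower and 1 higher. Caveola and vesicle genes had a median of 0.71 (percentile 100.0, alternatives 0.32 to 1.01), with Ehd2 at 1.57, Prkcdbp at 1.23 and Cav1 at 0.71, and Notch a median of 0.83 (percentile 100.0, alternatives 0.42 to 1.17). TGF-beta/BMP had 0.44 (99.7, alternatives 0.30 to 0.55) and leukocyte adhesion and inflammation 0.56 (99.4), with plate medians of 0.11 to 0.26 and, depending on the variable genes and the resolution, values from -0.10 to 1.89. VEGF and TIE receptor signalling had -0.33 (0.9, alternatives -0.55 to -0.15), which lay outside its plate medians of -0.28 to -0.12. Wnt/beta-catenin had -0.25 (0.5, alternatives -0.41 to -0.11), shear response 0.30 (95.1; 1.29 to -0.20 over plates, alternatives 0.14 to 0.595) and basement membrane -0.01 (47.9, alternatives -0.17 to 0.064). Hypoxia and glycolysis had -0.16 (12.6, alternatives -0.30 to -0.053), junctions -0.05 (39.2, alternatives -0.15 to -0.016) and immediate early genes 0.22 (97.7; 1.25 to -0.50 over plates, alternatives -0.038 to 0.51).

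In the list median, venous-like cells had more transcripts of inflammation genes than the capillary-marker clusters, by an amount that varied with plate and clustering. The 8 list members that are venous markers were left out of this median. The leukocyte adhesion and inflammation median was 2.21 (percentile 100.0) with 6 of 10 members higher and 0 lower, and with 1.48, 3.64, 0.78 and 0.06 on plates 521 to 524. It was 0.41 with plate-different genes kept among the variable genes. The chemokine Cxcl10 was at 4.50, Cd74 at 2.86 and the chemokine Cxcl1 at 1.94. Few cells carried these transcripts: over all cells, 2.61%, 4.38% and 8.34% had a read of them at fixed depth. The cyclooxygenase Ptgs2 led the held-out genes (93.4 against 1.37 CPM, log2 ratio 5.32), followed by Adgrg6 (4.89), Lama1 (4.29), Cdh26 (3.24), the protease inhibitor Timp2 (3.24) and Gpm6a (3.02). Ptgs2 had a read at fixed depth in 15.4% of venous-like cells. Slc26a10 (-4.25), the deacetylase Hdac9 (-3.24), Magix (-3.14), Arhgef25 (-3.11), Alpl (-3.00) and the netrin receptor Unc5b (-2.81) were lower, with Arhgef25 and Alpl in 3 of 4 plates. Arhgef25 turned to 0.089 at resolution 2.0. The weakest values under other settings were -0.90 for Slc26a10, -0.72 for Hdac9, -0.99 for Magix, -0.75 for Alpl and -0.85 for Unc5b. The higher genes stayed at 1.56 (Cdh26) or more. Immediate early genes had a median of 0.38 (percentile 100.0; 0.26 to 0.78 within plates, alternatives 0.043 to 0.845) and caveola genes 0.45 (99.8; 0.30 to 0.41 within plates, alternatives 0.30 to 0.53). Shear response had 0.22 (95.8, alternatives -0.025 to 0.36) and barrier transporters -0.12 (7.2, alternatives -0.27 to -0.060). Wnt/beta-catenin had -0.21 (0.5; 0.04, -0.28, -0.083 and 0.03 on plates 521 to 524, with 0 of 14 members 1.5-fold apart, alternatives -0.27 to -0.008) and VEGF and TIE receptor signalling -0.26 (1.0, alternatives -0.38 to -0.14). Notch had -0.19 (7.7; -0.97 to 0.26 within plates, alternatives -0.60 to -0.042), TGF-beta/BMP -0.19 (6.6, alternatives -0.23 to 0.055) and basement membrane -0.17 (3.7, alternatives -0.27 to -0.081). Hypoxia and glycolysis had -0.10 (15.9, alternatives -0.20 to 0.058) and junctions -0.04 (33.3, alternatives -0.13 to 0.12).

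In the list median pooled over plates, angiogenic-like cells had more transcripts of basement membrane genes than the capillary-marker clusters. The basement membrane median was 0.56 (percentile 100.0, alternatives 0.28 to 0.74) with 6 of 12 members higher and 0 lower, among them Lamb1 at 4.33 and Nid1 at 1.72, and with 0.68, 0.32 and -0.05 on plates 521 to 523. Hypoxia and glycolysis had 0.44 (99.6; 0.15 to 0.52 within plates), but turned to -0.126 with 4000 variable genes and was 0.198 with variable genes from all genes. Fscn1, which bundles actin (79.0 against 2.43 CPM, log2 ratio 4.54), Lamb1 (4.33), Prnd (3.93), Ptgs2 (3.84), Gng2 (3.83) and Sirpa (3.75) were highest, while Slc26a10 (-6.47), St8sia6 (-5.59), Rasd1 (0.079 against 37.4 CPM), Rhpn2 (-4.09), Arhgef25 (-4.05) and Alpl (-3.93) were lowest. Both classes lay unevenly on the plates, and of these 12 genes only Lamb1, Ptgs2, Sirpa, Slc26a10 and Rasd1 had the same direction in all 3 plates with enough cells. Pooling made some ratios larger than in any plate: Fscn1 was at 0.00 to 2.99 within plates and St8sia6 at -4.43 to 0.58. As the mean of the plates' own log2 ratios, Fscn1 was at 1.99, St8sia6 at -1.98 and Rasd1 at -2.16. Shear response had a median of -0.70 (percentile 0.1, alternatives -0.98 to -0.13) and immediate early genes -0.56 (0.0, alternatives -0.80 to -0.14), but within plates these ran from -0.59 to 0.57 and from -0.44 to 0.00. Other medians were 0.32 for caveola genes (97.7, alternatives 0.18 to 0.48), 0.31 for leukocyte adhesion and inflammation (94.8; -0.28 to 0.19 within plates, alternatives -0.12 to 1.29), 0.10 for Notch (71.5, alternatives -0.18 to 0.25) and 0.02 for VEGF and TIE receptor signalling (54.7, alternatives -0.023 to 0.31). They were -0.09 for TGF-beta/BMP (29.3, alternatives -0.50 to 0.22), -0.10 for barrier transporters (14.7, alternatives -0.30 to -0.051), -0.18 for Wnt/beta-catenin (3.0, alternatives -0.23 to 0.032) and -0.17 for junctions (5.2, alternatives -0.305 to -0.045).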

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

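Samples could not be paired, because no column carries a genotype or a replicate number; classes were also compared within plates. Alternatives on variable genes from all genes or from outside the random subset, on class markers kept in lists, on cells with markers of another cell type, on the mean of plates and, for ratios, on other resolutions and 4000 variable genes were chosen after seeing the data. A value counted as moved when it left the 95% binomial interval of a share or 1 SD of the plates' own values for a ratio, and as reversed when a value larger than that SD changed sign; the cause of such moves was not tested. Dropping the cell filter moved nothing, since it removed no cell, and says nothing about stability. TMM factors shifted ratios by at most 0.04 on the log2 scale. Where a plate was left out, class shares came from new clusters, but ratios kept the classes found with all plates, so these ratios do not test whether a class would be found again. Without that filter and these ratios, 582 of 660 alternative values of 48 list medians stayed, 71 moved and 7 reversed. Of 696 values of 60 ratios of named genes, 585 stayed, 109 moved and 2 reversed. Settings in which a compared class was not found gave no value and are not among these counts.

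At resolution 0.5 arterial-like cells were 18.8% and the capillary-marker share 62.3%, with no venous-like or angiogenic-like cluster. At resolution 2.0 arterial-like, venous-like, angiogenic-like and capillary-marker cells were 9.69%, 7.33%, 5.06% and 37.5%. With plate-different genes kept, angiogenic-like cells were 12.6% and capillary-marker cells 35.6%. With 4000 variable genes there was no venous-like cluster, and arterial-like, angiogenic-like and capillary-marker cells were 11.5%, 19.6% and 41.7%. With variable genes from all genes the shares were 18.5% arterial-like, 11.7% venous-like, 3.71% angiogenic-like and 50.4% capillary-marker, and from the genes outside the subset venous-like cells were 10.8%. Leaving out each plate in turn, the shares ran from 11.2% to 17.6% for arterial-like, 12.9% to 18.4% for venous-like, 8.69% to 19.6% for angiogenic-like and 31.3% to 46.1% for capillary-marker cells; no cluster was venous-like without plate 523 or without plate 524.

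Between arterial-like and venous-like cells, the Notch median of 1.01 was 1.54 from each cell's own CPM, 1.52 after thinning, 1.53 with no filter on low values, 1.72 at resolution 2.0, 1.38 with class markers kept and 1.44 as the mean of plates. Leukocyte adhesion and inflammation was -1.61 at resolution 2.0 and -0.079 with variable genes from outside the subset. Hypoxia and glycolysis was 0.089 with no filter on low values, -0.23 at resolution 2.0, and from -0.146 to 0.074 with each plate left out and the classes kept. Caveola and vesicle genes were 0.064 with variable genes from all genes. Of the 24 genes named between these classes, 17 moved with variable genes from outside the subset, among them Syt15 (5.63 to 1.59), P2ry2 (5.52 to 1.34) and Mannr (5.91 to 1.89), and Cd74 turned from -4.10 to 0.26; 10 moved with variable genes from all genes and 8 at resolution 2.0. A prior of 5 CPM moved 16, such as Col18a1 from 7.10 to 5.22. Between venous-like cells and the capillary-marker clusters, resolution 2.0 turned TGF-beta/BMP to 0.055, hypoxia and glycolysis to 0.058 and Arhgef25 to 0.089; hypoxia and glycolysis was also 0.022 with plate-different genes kept and 0.016 from outside the subset, and shear response -0.025 with variable genes from all genes. With plate-different genes kept, leukocyte adhesion and inflammation fell from 2.21 to 0.41. Between arterial-like cells and the capillary-marker clusters this list was 0.003 at resolution 0.5, 0.012 with plate-different genes kept and 1.893 from outside the subset, and turned to -0.10 with 4000 variable genes, which also turned hypoxia and glycolysis to -0.13 between angiogenic-like cells and these clusters (0.198 with variable genes from all genes).

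Shares of cells with a read followed depth. At 100000 reads they were 60.5% for Pdgfb, 65.4% for Vwf, 31.3% for Angpt2 and 8.76% for Rgs5. Pdgfb was 56.4% at 50000 reads. Without thinning they were 65.5%, 72.4%, 40.9% and 10.7%, and counting cells with at least 5 reads 51.6%, 59.9%, 23.6% and 6.40%.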

Other observations

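The tests of sampling as the whole cause and of genotype or animal were chosen only after results had been seen; the plate structure and the pericyte transcripts had been noticed in the data before any test.

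Cluster 7 was the largest of the 9 clusters, with 223 cells, of which 124, 87, 6 and 6 lay on plates 521 to 524. Its leading genes, some of which formed the cluster, included Slc22a14, Cyp4b1, Bgn, Fgfbp1 and Bmp4. Of its detected markers, 6 of 10 venous (median log2 ratio 0.858 to all other cells) and 4 of 8 angiogenic ones (0.22) were at least 1.5-fold higher, but none was among its 10 leading genes, so it stayed unnamed. Among held-out genes ranked against the capillary-marker clusters, the fatty acid hydroxylase Cyp4b1 (100.7 against 0.341 CPM) and the transporter family member Slc22a14 (87.1 against 0.65 CPM) were highest, followed by Plagl1 (29.3 CPM against 3 reads), Cdh26, Ptgs2 and Cxcl16. Within plates 521 and 522, log2 ratios were between 4.93 and 6.28 for Cyp4b1 and between 4.19 and 5.45 for Slc22a14. The leukocyte adhesion and inflammation list had a median of 2.39, with 1.05 on plate 521 and 3.11 on plate 522. Lower over all cells were Lrrn3 (-3.50), Rasd1 (-3.44), Zap70 (-2.84), Palm (-2.78), Alpl (-2.74) and Ptprr (-2.63). Within these plates most were closer to 0, with -1.80 to -1.14 for Lrrn3, -0.80 to -0.51 for Rasd1, -2.97 to -2.34 for Zap70, -1.48 to -1.43 for Palm, 0.04 to 3.11 for Alpl and -1.51 to -1.24 for Ptprr. With 6 cells on each of plates 523 and 524, fewer than the 10 required, the cluster was not compared within these, and whether it is a kind of cell or follows plate, genotype or animal stayed open.

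Some genes differed widely between plates; those named here were chosen after their values were seen. From plate 521 to 524, Angpt2 was at 507.6, 298.9, 48.4 and 29.9 CPM, Apln at 341.2, 200.5, 0.0097 and 3.78 CPM, Plvap at 20.8, 15.3, 0.573 and 1.41 CPM and Vwf at 1582, 1094, 400.8 and 259.2 CPM. Other markers of sprouting or venous endothelium differed little or ran the other way, with Dll4 at 203.4, 248.0, 253.4 and 186.4 CPM, Cd34 at 938.7, 1116, 1216 and 1396 CPM, Ephb4 at 89.0, 117.2, 117.5 and 140.1 CPM and Plaur at 20.9, 15.6, 28.4 and 24.5 CPM. The lipid transporter Mfsd2a was at 197.7, 533.3, 853.4 and 851.5 CPM. Vtn was at 8.90, 2.49, 34.8 and 20.0 CPM and Rgs5 at 1.18, 12.4, 82.0 and 34.5 CPM. Xist stood at 571.4 CPM or more on each plate. Of the Y-linked genes, Ddx3y stood at 0.110 CPM or less, Eif2s3y at 0.182 CPM or less, Uty at 0.871 to 1.90 CPM and Kdm5d at 5.50 to 10.7 CPM, with a read in 37.3% of cells at fixed depth for Kdm5d and 11.7% for Uty. Pairs of plates had between 203 (521 and 522) and 769 (521 and 524) genes over 2-fold apart, with 239 between 523 and 524.

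Of 9059 genes at 20 CPM or more on a plate, 1395 were over 2-fold apart between some plates. Random deals of the cells gave at most 523 such genes. By the bounds set beforehand, this decided neither for nor against sampling of few cells as a cause. Of the same deals, 0 of 20 reached 1395, which argues against sampling as the whole cause, a question added afterwards. Sampling could give part of the count. A different mix of vessel zones was tested on 1167 genes picked outside the arterial-like cluster: between the same plates their median log2 ratio was 1.28 outside and 0.446 inside it, between the bounds set for either answer. Genotype or animal could not be told apart from plate, because 0 columns name either. Plates 521 and 522 together hold as many columns as there are ret/+ labels (590), and plates 523 and 524 as many as there are ret/ret labels (597). Yet Vtn and Rgs5 were lower, and Angpt2 higher, on plates 521 and 522 than on plates 523 and 524. The genotype short of pericytes is ret/ret, but what it does to these transcripts in sorted cells could not be tested. The values therefore cannot settle an assignment. Neither number nor values were used, so that no plate-dependent value, cluster 7 and class shares included, is given as an effect of genotype.

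Pericyte transcripts were read in sorted cells although the gate removes Cspg4-positive cells. Cells with at least 3 of the 12 pericyte markers at 100 CPM or more held 27.8% of these markers' reads. This lay under the bound set beforehand for arguing against whole pericytes or doublets as the main source. Cells with fewer markers at that level were counted as neither, and whether a doublet would reach 3 markers was not tested. The test therefore cannot exclude doublets. Free RNA alike in all wells may account for plate 524, where the highest over the lowest cluster share of cells with such a read was 1.31. This ratio was 1.88, 12.9 and 9.00 on plates 523, 522 and 521, with few cells per cluster. On plate 522 the highest share (34.8%, 16.4% to 57.3%) and the lowest (2.70%, 0.07% to 14.2%) had intervals that did not overlap. The bound set beforehand against this source asked for a large ratio on every plate, so the test left it open. Expression by endothelial cells themselves was not tested.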
